A study of Mus musculus with 14 samples.

How the data were processed

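Per the labels, RNA of left ventricles was extracted with an RNeasy kit and QIAzol, messenger RNA was taken up on poly(A) beads, and libraries were made with a Swift Biosciences kit. The submitters' notes name Bowtie2 2.1.0, RSEM 1.2.15 and the mouse genome mm10 (GRCm38), without the role or order of the steps, the gene annotation, the filters or the read layout. RSEM is a program that divides reads between genes by expectation maximisation, and the deposited table holds expected counts, of which between 15.1% and 16.4% per library were not whole numbers. It has 24054 genes, 27 of them under names that a spreadsheet had turned into dates, and none named as encoded in mitochondria. Columns were matched to samples by the library number, which is each sample's description. HFpEF-scr 1 has number 6 and HFpEF-scr 2 number 8, and the table holds no library with the number between them.

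Expected counts were rounded to whole numbers and tested in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr on the groups, which left 13588, and libraries were scaled by TMM. A quasi-likelihood fit with 1 coefficient per group took in all 14 libraries, and each comparison was a contrast of it with a two-sided F-test. Adjusted p are Benjamini-Hochberg values over all genes tested, and a gene was called under 0.05. Each SE was computed from the fold change and its F statistic. CPM are counts per 1000000 after TMM. The common biological coefficient of variation was 0.0999. Replicate numbers were not used as a block, because the labels do not say that they mark a shared litter or day.

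A set of 43 gene lists was fixed before the data were examined, covering processes of heart muscle, fuel use, stress, immunity, matrix and cell division, and 12 sets of markers of cell types or tissues that a piece of ventricle could hold. Of 849 listed symbols 824 were found as such, 7 under an older symbol and 18 not at all. Lists with at least 4 measured members were tested with camera in limma 3.58.1, which compares a list with all other genes, with a preset correlation between members of 0.01. Those adjusted p run over the 37 lists of each comparison, and the test was repeated with a correlation estimated for each list. Counts adjusted over the list alone use Benjamini-Hochberg within the list. A list's score in a library is the mean log2 CPM of its members, with a prior count of 2, less the mean over the controls.

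The rule for named genes was also fixed beforehand. It took Foxo1, the 10 largest called rises and falls of each comparison among genes with a mean of at least 2 CPM over all 14 libraries, no overlap of the 2 groups and a symbol that is not a model name, up to 4 members of each list with the smallest p, and the 10 genes with the strongest change back. From the members of lists, those with a well-known role were preferred for the text, and that choice was made after their values were seen. Of the genes that the rule took, 1 is not reported here. Positions are those of GENCODE vM21 on GRCm38, and exons shared with other genes were counted there.

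Results were also computed with DESeq2 size factors, without a filter on low counts, with at least 10 counts in every library, with the replicate number as a block and without each library of the compared groups in turn, and those of single comparisons in fits of the groups compared. Results on genes, but not on lists, were further computed with DESeq2 1.42.0 and with limma voom with and without quality weights, counts and named genes also against a fold of 1.2, and the correlation of fold changes with limma voom alone among these. After the data were seen, 4 settings were added, namely the immediate early score as a covariate, the clock index as a covariate, leaving out HFpEF-scr 1 and 2 together, and counts thinned to the smallest total. Chance was gauged by 100 of the splits of the compared libraries into groups of the same sizes. The shared HFpEF-scr libraries were dealt with by 40 simulated data sets without change and by fits with separate HFpEF-scr libraries.

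The method was tested on simulated data with the totals and spread of these libraries. Of genes given a 1.5-fold change it recovered 73%, 74% and 71.4% in the 3 comparisons, and of those given a 2-fold change 87.2%, 88% and 90%, all in the right direction. False calls made up 3.73%, 4.14% and 5.39% of calls. A shift of 0.3 log2 in 1 list was recovered in each comparison. Y-linked genes were seen in every library, and no pair of libraries of the same group was a duplicate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Reads were not used here, so no statement is made on isoforms or on the virus itself.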

Results

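Messenger RNA of the mouse left ventricle was sequenced in 14 libraries, which the labels place in 3 groups. The 5 control libraries came from mice on a standard diet, labelled 10 weeks. The other 9 came from mice on a high-fat diet with L-NAME, a blocker of nitric oxide synthases, a pairing used to bring about heart failure with preserved ejection fraction (HFpEF). These mice also received an adeno-associated virus (AAV) carrying a short hairpin RNA. In the 4 HFpEF-scr libraries the hairpin had a scrambled sequence, and in the 5 libraries labelled HFpEF-FoxO1-sh it was directed at Foxo1, which encodes a transcription factor held out of the nucleus by insulin signalling. Both HFpEF groups are labelled with 6 weeks of diet and 4 weeks of AAV, and no AAV is named for the controls. The labels do not state that the replicates are separate animals, so each p measures the spread between these libraries.

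The files gave expected counts per gene. Totals of the controls 1 to 5, in units of 1000000 counts (M), were 21.25, 13.17, 15.11, 14.80 and 14.84 M, those of HFpEF-scr 1 to 4 were 14.03, 14.40, 15.38 and 14.29 M, and those of HFpEF-FoxO1-sh 1 to 5 were 15.38, 13.64, 14.63, 14.15 and 15.21 M. Between 16094 and 16509 genes had a count in each library, and 13588 genes were tested. Levels are given as counts per 1000000 (CPM) and changes as log2 fold changes ± SE, with positive values for the group named first. A gene was called changed at an adjusted p under 0.05 over all genes tested. The gene lists were fixed before the data were examined, and 37 of them had enough measured members for a list test.

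Foxo1, the gene targeted by the hairpin, lies on chromosome 3 at 52268336 to 52353221 of GRCm38, on the plus strand. Its level in the controls 1 to 5 was 44.2, 42.2, 42.4, 47.0 and 44.4 CPM, with a mean of 44.0 ± 1.93 (SD, n = 5). The HFpEF-scr libraries 1 to 4 had 44.8, 48.3, 41.0 and 40.1 CPM, a mean of 43.5 ± 3.74 (SD, n = 4). In the libraries labelled HFpEF-FoxO1-sh, replicates 1 to 5 had 41.5, 46.0, 39.3, 43.8 and 41.4 CPM, a mean of 42.4 ± 2.56 (SD, n = 5). The log2 fold change of HFpEF-FoxO1-sh against HFpEF-scr was -0.04 ± 0.06 (adjusted p = 0.780), with a 95% interval from a fall of 10.9% to a rise of 6.42%. HFpEF-scr against control gave -0.02 ± 0.06 (adjusted p = 0.904) with an interval from -9.52% to 8.04%. The series title speaks of an upregulated FoxO1, and the largest rise of the transcript that this interval allows is 8.04%. That value covers RNA of ventricles with AAV against controls for which no AAV is named. It does not speak to the protein or its activity. HFpEF-FoxO1-sh against control gave -0.05 ± 0.06 (adjusted p = 0.583). Each library held between 566 and 944 counts of Foxo1. Of the other FoxO genes, Foxo4 rose by 0.25 ± 0.06 in HFpEF-scr against control (adjusted p = 0.0157) and Foxo6 fell by 0.85 ± 0.23 (adjusted p = 0.0323), while Foxo3 gave -0.02 ± 0.13. The call of Foxo4 was lost without HFpEF-scr 4 (adjusted p = 0.0514), and that of Foxo6 in 6 of 9 refits without 1 library, most of all without HFpEF-scr 2 (adjusted p = 0.0858).

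**Figure D1:**
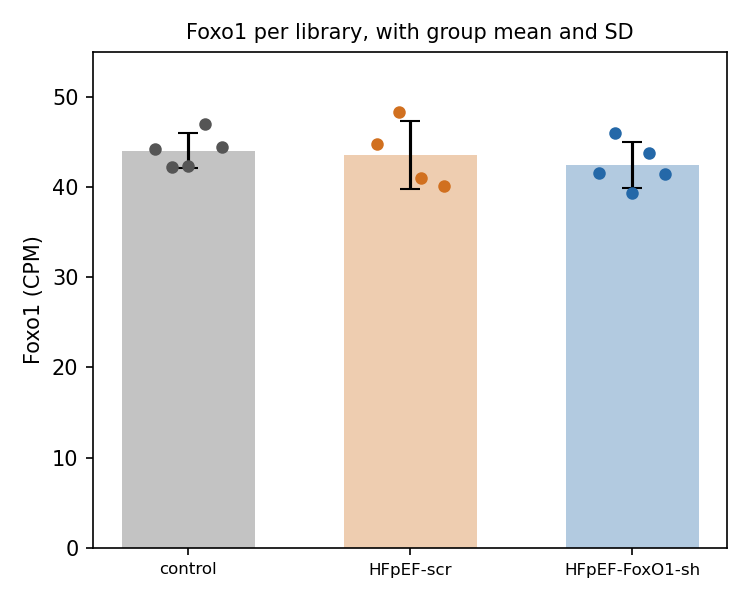
Foxo1 in counts per 1000000 (CPM) in each of the 14 libraries, by group, with the group mean as a bar and the SD as whiskers. The group means were 44.0, 43.5 and 42.4 CPM.

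HFpEF-scr against control asks which genes differ between hearts under the HFpEF regime with a scrambled hairpin and hearts on a standard diet. Of 23 genes of fatty acid oxidation 16 rose in HFpEF-scr, and that list was called only at the preset correlation (adjusted p = 0.330 with an estimated correlation). Pdk4, an inhibitor of glucose-derived pyruvate oxidation, rose by 1.50 ± 0.24 (adjusted p = 0.00192), and Acot1, an acyl-CoA thioesterase, by 1.65 ± 0.19. Called falls took in 3 of 26 genes of the cell cycle, 5 of 15 of antigen presentation and 7 of 22 of the sarcomere, lists that were not called with an estimated correlation (adjusted p = 0.347, 0.347 and 0.324). Mki67, a marker of dividing cells, fell by 1.26 ± 0.29. In all, 1001 genes changed, 498 up and 503 down, of which 29 rose and 36 fell by at least 2-fold.

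Among called genes whose values in the groups did not overlap, large rises were those of Slc15a2, Chrna2, Pde11a, Acot1, Pdk4, Tcf23, Ddit4, Mmp3 and Lgals4, from 2.61 ± 0.59 for Slc15a2 to 1.04 ± 0.16 for Lgals4. Chrna2, a nicotinic receptor subunit, rose by 2.06 ± 0.23 (adjusted p = 8.24e-05), and Pde11a, a phosphodiesterase of cyclic nucleotides, by 1.90 ± 0.27 (adjusted p = 5.95e-04). The 10 largest falls of that kind were Erdr1, Lgi3, Abat, C7, Prnd, Scgb1c1, Lrrc4b, Mki67, Gnb3 and Epn3, from -3.03 ± 0.75 for Erdr1 to -1.15 ± 0.10 for Epn3. Abat, which encodes the transaminase that breaks down GABA, fell from 39.6 to 13.5 CPM, a log2 fold change of -1.55 ± 0.18 (adjusted p = 1.26e-04). C7, a component of the complement attack complex, fell by 1.44 ± 0.30. In GRCm38, Pdk4 lies on chromosome 6 at 5483351 to 5496309 and Abat on chromosome 16 at 8513429 to 8621568. The annotation shares 97.2% of the exon bases of Prnd with a readthrough gene, and reads of Acot1 may be divided with its close paralog Acot2. Calls lost in some refits without 1 library were those of Ddit4 (adjusted p up to 0.0857, without HFpEF-scr 2), Erdr1 (0.0689, HFpEF-scr 4), Mmp3 (0.0656, HFpEF-scr 1), Slc15a2 (0.0559, HFpEF-scr 4) and Mki67 (0.0516, HFpEF-scr 2).

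**Figure D2:**
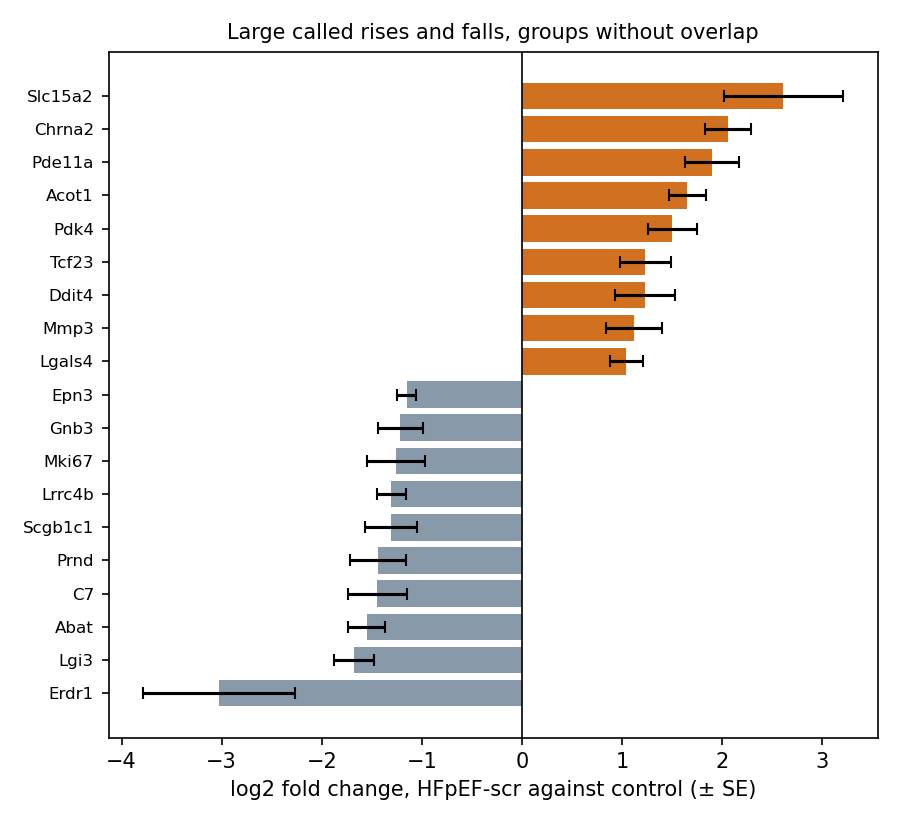
Log2 fold change of HFpEF-scr against control for the named large rises and falls among called genes without overlap of the groups, with the SE as whiskers. Erdr1, which fell by 3.03, has the widest SE.

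Of the 23 genes of fatty acid oxidation tested, 16 rose and none fell in HFpEF-scr, with a median of 0.30, and 19 rose and 2 fell when adjusted over the list alone. Decr1, a reductase needed to oxidise unsaturated fatty acids, rose by 0.70 ± 0.06 (adjusted p = 1.1e-05), Hadhb, part of the trifunctional protein, by 0.39, and Acadvl, the first dehydrogenase of long chains, by 0.35. The list test against other genes gave adjusted p = 3.66e-14 with the preset correlation and adjusted p = 0.330 with an estimated correlation. Of the 30 genes of lipid handling and PPAR targets, 12 rose and none fell, and 18 rose and 2 fell when adjusted over the list alone. The fatty acid carriers Cd36 and Fabp3 rose by 0.49 ± 0.05 and 0.46, and the lipid droplet gene Cidea by 0.71. That list had a median of 0.29 and adjusted p = 7.04e-09, or adjusted p = 0.300 with an estimated correlation. No list called in HFpEF-scr against control held with an estimated correlation, which gave adjusted p from 0.300 to 0.471 for the 18 called lists.

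Of 25 genes of glycolysis and glucose uptake 7 fell and 2 rose, or 12 and 2 when adjusted over the list alone, with a median of -0.13 (list adjusted p = 2.55e-04, and adjusted p = 0.365 with an estimated correlation). The muscle enolase Eno3 fell by 0.43 ± 0.05, the lactate dehydrogenase subunit Ldhb by 0.30 ± 0.03, and Pdk1, another inhibitor of pyruvate dehydrogenase, rose by 0.30 ± 0.04. Among 65 nuclear genes of oxidative phosphorylation 7 fell and 1 rose, or 11 and 1 when adjusted over the list alone. Cox7a1, a subunit of cytochrome oxidase in muscle, fell by 0.33 ± 0.04 and Ndufa11, a subunit of complex I, by 0.29. The median of that list was -0.06 (adjusted p = 3.53e-05, and adjusted p = 0.471 with an estimated correlation). Of 19 genes of branched-chain amino acid breakdown 3 fell, and 6 when adjusted over the list alone, with a median of -0.10 (list adjusted p = 2.18e-05, and adjusted p = 0.347 with an estimated correlation). Bckdhb, a subunit of the dehydrogenase that commits these acids to breakdown, fell by 0.42 ± 0.05.

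Of 22 sarcomere genes 7 fell and none rose, and 11 fell when adjusted over the list alone. They included Mybpc3, cardiac myosin-binding protein C, by 0.37 ± 0.05, the light chain Myl3 by 0.33 ± 0.04 and the troponin C gene Tnnc1 by 0.31. The list had a median of -0.13 (adjusted p = 1.09e-05, and adjusted p = 0.324 with an estimated correlation). In the same comparison all 15 fibroblast markers and 11 of 13 markers of pericytes and smooth muscle lay above 0, and for these falls, as for those of respiration, glycolysis and branched-chain genes, the share of muscle RNA was not separated from a change within muscle cells. Of 40 ion channel genes 4 rose and 4 fell, or 7 and 7 when adjusted over the list alone, and the list was not called (adjusted p = 0.442). Scn4b, a sodium channel beta subunit, rose from 66.8 to 123 CPM, by 0.88 ± 0.09 (adjusted p = 3.29e-05), and Kcnv2, a modifier of voltage-gated potassium channels, rose by 0.72 ± 0.12 (adjusted p = 0.00268). Kcnip2, a subunit of the channels of the transient outward current, fell by 0.52 ± 0.08 (adjusted p = 0.0011), and Gja1, the gap junction protein connexin 43, by 0.32 ± 0.07 (adjusted p = 0.00972). In GRCm38 Scn4b lies on chromosome 9 at 45138395 to 45154152 and Kcnip2 on chromosome 19 at 45791839 to 45816061. Of 32 calcium handling genes 1 rose and 2 fell, the same when adjusted over the list alone, without a call for the list (adjusted p = 0.704). Ank2, an ankyrin that anchors ion transporters, fell by 0.17 ± 0.04. Of 17 hypertrophic stress genes 1 rose, Fhl1, which encodes a protein with LIM domains, by 0.34 ± 0.06, with 1 when adjusted over the list alone and a list adjusted p = 0.184.

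Some genes of antigen presentation, the interferon response and the cell cycle were lower in HFpEF-scr. Of 15 antigen presentation genes 5 fell and none rose, and 9 fell when adjusted over the list alone, with a median of -0.33 (list adjusted p = 1.09e-05, and adjusted p = 0.347 with an estimated correlation). The class I heavy chain H2-K1 fell by 0.46 ± 0.10. Of 31 interferon response genes 3 fell, among them the interferon-induced GTPase Iigp1 by 0.83 ± 0.14, and 9 fell when adjusted over the list alone. Its median was -0.22 (adjusted p = 2.15e-05, and adjusted p = 0.330 with an estimated correlation). Of 26 cell cycle genes 3 fell, and 7 when adjusted over the list alone, with a median of -0.54 (list adjusted p = 1.09e-05, and adjusted p = 0.347 with an estimated correlation). These included the cyclin-dependent kinase gene Cdk1, whose log2 fold change was -1.44. Its call was lost in 2 of the 5 refits that tested it (adjusted p up to 0.0838, without HFpEF-scr 2). In the other refits without 1 library it did not pass the filter on low counts. Macrophage markers gave no call for the list (adjusted p = 0.349), and 1 of 19 rose, the same when adjusted over the list alone.

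Immediate early genes, which respond to stimuli within minutes, differed between libraries of the same group. Of 23 tested, 6 rose in HFpEF-scr and none fell, and 10 rose when adjusted over the list alone, with all 23 above 0 and a median of 0.77 (list adjusted p = 6.94e-07, and adjusted p = 0.374 with an estimated correlation). Without 1 library that median ran from 0.53 to 1.30. Fosb, a subunit of the AP-1 transcription factor, rose by 4.95 ± 0.96 (adjusted p = 0.0067) and lies on chromosome 7 at 19302696 to 19310051. The mean log2 CPM of these genes, the immediate early score, ran from 3.57 to 6.16 over the controls, from 4.85 to 6.93 over HFpEF-scr and from 3.67 to 5.76 over HFpEF-FoxO1-sh. Its difference of 1.21 between HFpEF-scr and control, with overlap of the groups, gave an exact permutation p = 0.0952 (adjusted p = 0.190). With that score as a covariate 396 genes changed in place of 1001, a setting chosen after the data were seen. Among 20 genes of cytokines and NF-kB targets 2 rose, and 4 when adjusted over the list alone, with a median of 0.39 (list adjusted p = 0.00848, and adjusted p = 0.365 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 2.31 ± 0.48 (adjusted p = 0.0094). Leaving out HFpEF-scr 1 ended that list's call (adjusted p = 0.144).

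Stromal markers moved the same way. Of 15 fibroblast markers 3 rose, 4 when adjusted over the list alone (list adjusted p = 1.58e-04, and adjusted p = 0.347 with an estimated correlation), and of 13 markers of pericytes and smooth muscle 3 rose, 6 when adjusted over the list alone (list adjusted p = 0.00112, and adjusted p = 0.300 with an estimated correlation). Of 41 genes of extracellular matrix and fibrosis 1 rose, the small leucine-rich proteoglycan Lum, by 0.49 ± 0.10, with 1 when adjusted over the list alone. Lum is also a fibroblast marker here, as are Col1a1, Col1a2, Col3a1 and Dcn of the matrix list. The matrix list had a median of 0.10 (adjusted p = 0.00732, and adjusted p = 0.431 with an estimated correlation) and lost its call without HFpEF-scr 3 (adjusted p = 0.0696). Of 26 FoxO target genes 5 rose and none fell, and 6 rose when adjusted over the list alone, with a median of 0.09 (list adjusted p = 0.0147, and adjusted p = 0.419 with an estimated correlation). They included Cat, the peroxide-degrading enzyme catalase, by 0.48 ± 0.06. The call of the FoxO target list was lost without control 1 (adjusted p = 0.0764), without HFpEF-scr 2 (0.0650) and without HFpEF-scr 4 (0.0718).

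Of 15 genes of the glucocorticoid response 4 rose, the same when adjusted over the list alone, with a median of 0.69 (list adjusted p = 1.58e-04, and adjusted p = 0.347 with an estimated correlation). Of 15 genes of the hypoxia response 4 rose and 1 fell, 8 and 1 when adjusted over the list alone, with a median of 0.24 (list adjusted p = 0.00208, and adjusted p = 0.365 with an estimated correlation). The member that fell was Slc2a1, a glucose transporter, by 0.67 ± 0.13. Of 17 heat shock genes 2 rose, 4 when adjusted over the list alone, with a median of 0.12 (list adjusted p = 0.00370, and adjusted p = 0.382 with an estimated correlation), and Hspa1a rose by 1.50 ± 0.30. Red cell genes stood apart in HFpEF-scr 1, where Hbb-b1, a beta globin gene, reached 2364 CPM, and the list of red cell markers was not called in HFpEF-scr against control (adjusted p = 0.822, with a median of 1.01). Without HFpEF-scr 1 that list turned down, with a median of -0.68 (adjusted p = 0.00445).

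The count of 1001 genes fell to 643 without control 2, 537 without control 3, 598 without HFpEF-scr 2 and 546 without HFpEF-scr 4. It was 504 in a fit of the 2 groups alone and 56 against a fold of 1.2.

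HFpEF-FoxO1-sh against HFpEF-scr asks what differs between hearts under the same regime by the hairpin, as labelled. Of the matrix genes 21 of 41 fell in the libraries labelled HFpEF-FoxO1-sh, the only list also called with an estimated correlation (adjusted p = 0.0433). Called as well were falls of 5 of 19 macrophage markers and small rises of 20 of 65 genes of respiration and 3 of 23 of fatty acid oxidation (list adjusted p = 0.191, 0.135 and 0.294 with an estimated correlation). Col3a1, which encodes a fibrillar collagen, fell from 254 to 121 CPM, by 1.07 ± 0.12 (adjusted p = 1.49e-04), and Col6a3, a chain of microfibril collagen, by 0.91 ± 0.08 (adjusted p = 4e-05). Ankrd23, a stretch-responsive protein of the sarcomere, fell by 0.87 ± 0.14 (adjusted p = 0.0042). Sdhb, the iron-sulfur subunit of complex II, rose by 0.17 ± 0.03 (adjusted p = 0.0107). In all, 486 genes changed, 179 up and 307 down, of which 2 rose and 30 fell by at least 2-fold. Foxo1 itself was not called between these groups, so each direction is that of the libraries labelled HFpEF-FoxO1-sh, whatever their level of FoxO1.

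The 10 largest called rises without overlap of the groups were Inmt, Grhl2, Osgin1, Aldh1l1, Klhl33, Cngb3, Mid1ip1, Frat1, Flt3l and Cyp4f17, from 1.50 ± 0.28 for Inmt to 0.60 for Cyp4f17. Inmt, a methyltransferase of indole amines, went from 6.12 to 17.3 CPM (adjusted p = 0.0105), and Mid1ip1, an activator of fatty acid synthesis, rose by 0.67 ± 0.13 (adjusted p = 0.011). The 10 largest falls of that kind were Nr4a3, Arntl, Cdkn1a, Hspa1a, Ccl2, Nppb, Itgam, Itgb3, Col5a3 and Adam19, from -2.38 ± 0.49 for Nr4a3 to -1.14 ± 0.20 for Adam19. Cdkn1a, an inhibitor of cyclin-dependent kinases, went from 28.8 to 7.01 CPM, a fall of 2.03 ± 0.42 (adjusted p = 0.0171). Nppb, which encodes B-type natriuretic peptide, went from 97.9 to 38.9 CPM, a fall of 1.34 ± 0.30 (adjusted p = 0.0244). In GRCm38 Col3a1 lies on chromosome 1 at 45311538 to 45349706, Nppb on chromosome 4 at 147985788 to 147987205 and Cdkn1a on chromosome 17 at 29090976 to 29100727. Reads of Hspa1a may be divided with Hspa1b, and 68.7% of the exon bases of Itgam are shared with another annotated gene. Of these 20 genes, Inmt, Osgin1, Klhl33, Cngb3, Mid1ip1, Itgb3 and Adam19 kept their calls in all 9 refits without 1 HFpEF library. Nr4a3, Cdkn1a and Col5a3 lost theirs without HFpEF-FoxO1-sh 1 alone (adjusted p = 0.0528 for each). The others lost theirs in 4 to 9 of 9 refits, with adjusted p up to 0.132 for Arntl without HFpEF-scr 2, 0.102 for Ccl2 without HFpEF-scr 1 and 0.0661 for Nppb without HFpEF-scr 1. Of 45 genes named for this comparison here and below, 5 kept their calls with the clock index as a covariate, 8 without both HFpEF-scr 1 and 2, and 27 with the immediate early score as a covariate. With the clock index the adjusted p of these 20 ran from 0.161 for Itgam to 0.622 for Arntl, and without both HFpEF-scr 1 and 2 only Itgb3 of the 20 kept its call (adjusted p = 0.0380). These 3 settings were chosen after the data were seen.

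Of 41 genes of extracellular matrix and fibrosis 21 fell and none rose, and 31 fell and 1 rose when adjusted over the list alone, with a median of -0.64. Besides Col3a1 and Col6a3 these included Col6a2, by 0.75 ± 0.07 (adjusted p = 4e-05), Col1a1, a chain of the main fibrillar collagen, by 0.80 ± 0.08 (adjusted p = 8.89e-05), and Loxl1, which cross-links elastin, by 0.67 ± 0.07 (adjusted p = 8.89e-05). The list gave adjusted p = 4.47e-24, and adjusted p = 0.0433 with an estimated correlation, the only list of the 18 called here to hold under it. Its mean log2 CPM relative to the controls lay between 0.05 and 0.20 in the HFpEF-scr libraries and between -0.50 and -0.26 in the libraries labelled HFpEF-FoxO1-sh. Stromal and immune markers moved with it. Of 15 fibroblast markers 3 fell, 5 when adjusted over the list alone, with a median of -0.24 (list adjusted p = 2.88e-07, and adjusted p = 0.177 with an estimated correlation). These markers share Col1a1, Col1a2, Col3a1, Dcn and Lum with the matrix list, so their fall is partly that of the same genes. The 6 fibroblast markers that encode no matrix protein had a median of -0.14. Of 13 markers of pericytes and smooth muscle 4 fell when adjusted over the list alone, and the list had a median of -0.22 (adjusted p = 4.90e-04, and adjusted p = 0.135 with an estimated correlation). Of 19 macrophage and monocyte markers 5 fell, 13 when adjusted over the list alone, with a median of -0.40 (list adjusted p = 3.31e-08, and adjusted p = 0.191 with an estimated correlation). Emr1, the macrophage surface protein F4/80, fell by 0.71 ± 0.14 (adjusted p = 0.0135).

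Of 20 genes of cytokines and NF-kB targets 5 fell, 12 when adjusted over the list alone, with a median of -0.66 (list adjusted p = 6.26e-07, and adjusted p = 0.135 with an estimated correlation). They included Socs3, by 2.64 ± 0.49 (adjusted p = 0.0105), and Icam1, an adhesion molecule for leukocytes, by 0.72 ± 0.12 (adjusted p = 0.00669). Of 23 immediate early genes 5 fell, 8 when adjusted over the list alone, with a median of -0.85 (list adjusted p = 1.27e-05, and adjusted p = 0.575 with an estimated correlation). Without 1 library that median ran from -1.02 to -0.46. Fosb fell by 5.59 ± 1.03 (adjusted p = 0.00973), from 188 to 3.98 CPM. The immediate early scores of these groups overlapped, and their difference of -1.08 gave an exact two-sided permutation p = 0.127, or 0.190 adjusted over 6 such tests. Of 17 hypertrophic stress genes 4 fell, 5 when adjusted over the list alone, with a median of -0.29 (list adjusted p = 3.14e-04, and adjusted p = 0.161 with an estimated correlation). Besides Ankrd23 and Nppb they included Myh7, the slow myosin heavy chain, which went from 1530 to 519 CPM, a fall of 1.57 ± 0.39 (adjusted p = 0.038). Its call was lost in 7 of 9 refits (adjusted p up to 0.135, without HFpEF-scr 1). Another annotated gene shares 78.2% of the exon bases of Ankrd23.

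All 65 nuclear genes of oxidative phosphorylation had log2 fold changes above 0 in the libraries labelled HFpEF-FoxO1-sh. Of these 20 rose and none fell, and 61 rose when adjusted over the list alone, with a median of 0.14 (list adjusted p = 8.88e-26, and adjusted p = 0.135 with an estimated correlation). Of 23 genes of fatty acid oxidation 3 rose, 15 when adjusted over the list alone, with a median of 0.15 (list adjusted p = 2.55e-09, and adjusted p = 0.294 with an estimated correlation). Echs1, the enoyl-CoA hydratase of short chains, rose by 0.18 ± 0.03. In the same comparison all 15 fibroblast markers, all 13 of pericytes and smooth muscle and 17 of 19 of macrophages lay below 0, and a larger share of muscle RNA was not separated from a change within muscle cells. Of 19 genes of branched-chain amino acid breakdown 5 rose, 14 when adjusted over the list alone, with a median of 0.15 (list adjusted p = 3.78e-09, and adjusted p = 0.177 with an estimated correlation), and Bckdhb rose by 0.23 ± 0.05. Of 40 ion channel genes 1 rose, the same when adjusted over the list alone, and the list was not called (adjusted p = 0.288, with a mean of -0.01 below 0, a median of 0.04 above it and an upward test). That gene was Kcnh2, the pore subunit of the rapid delayed rectifier potassium channel, by 0.36 ± 0.07 (adjusted p = 0.0156), on chromosome 5 at 24319589 to 24351604. Of 32 calcium handling genes 1 fell, the same when adjusted over the list alone, with a list adjusted p = 0.559. Of 26 FoxO target genes 1 fell, 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.979). Its median of 0.02 and its upward test differed in sign from its mean of -0.13. The other 8 called lists were those of endoplasmic reticulum chaperones, glycolysis, nitric oxide and cGMP, cell cycle, heat shock proteins, autophagy, the hypoxia response and oxidative stress defence. They gave list adjusted p from 0.00789 to 0.0494, and adjusted p from 0.135 to 0.605 with an estimated correlation, and each lost its call without at least 1 library. In glycolysis 3 of 25 rose and 1 fell, or 6 and 1 when adjusted over the list alone.

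Clock genes, which cycle over the day, differed between libraries. Per3 and Tef were higher in each library labelled HFpEF-FoxO1-sh than in any other, from 73.8 CPM against at most 70.9 CPM and from 273 CPM against at most 252.8 CPM. Arntl, the activator of the clock on chromosome 7 at 113207465 to 113314126, lay between 1.34 and 2.02 CPM in them, between 2.41 and 15.7 CPM in HFpEF-scr and between 1.95 and 19.8 CPM in the controls. Its log2 fold change against HFpEF-scr was -2.35 ± 0.63 (adjusted p = 0.0491). Its partner Clock fell by 0.57 ± 0.14 (adjusted p = 0.0374) and the repressor Bhlhe40 by 0.53 ± 0.13 (adjusted p = 0.0388). These calls were lost in 8, 6 and 7 of 9 refits, with adjusted p up to 0.132, 0.0958 and 0.104 without HFpEF-scr 2, HFpEF-scr 2 and HFpEF-scr 3. Of 20 clock genes 3 fell and none rose, and 4 fell and 5 rose when adjusted over the list alone, with no call for the list (adjusted p = 0.254). A clock index, the mean log2 CPM of Arntl, Npas2 and Clock less that of Dbp, Per2, Per3 and Tef, lay between -4.61 and -4.20 in HFpEF-FoxO1-sh and between -3.75 and -1.50 in HFpEF-scr. The difference of -1.73 gave an exact two-sided permutation p = 0.00794, or 0.0238 adjusted over the 6 tests of both scores. Against the controls, between -4.07 and -1.06, the difference was -1.32 with the same exact p. The index was defined after the data were seen. Any complete separation of groups of these sizes gives that p, the lowest possible, so it is no independent test of the index. With the clock index as a covariate, chosen after the data were seen, 11 genes changed between HFpEF-FoxO1-sh and HFpEF-scr, all of them lower. The median absolute log2 fold change of the genes called without it went from 0.367 to 0.285. The median SE over all genes went from 0.0898 to 0.118. In that fit the matrix, respiration and macrophage lists were called at the preset correlation, with medians of -0.57, 0.12 and -0.45. Of the 18 lists called without the covariate 5 lost their calls, and 2 lists not called without it turned direction. Without the covariate an estimated correlation left only the matrix list called (adjusted p = 0.0433, against 0.135 and 0.191).

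**Figure D3:**
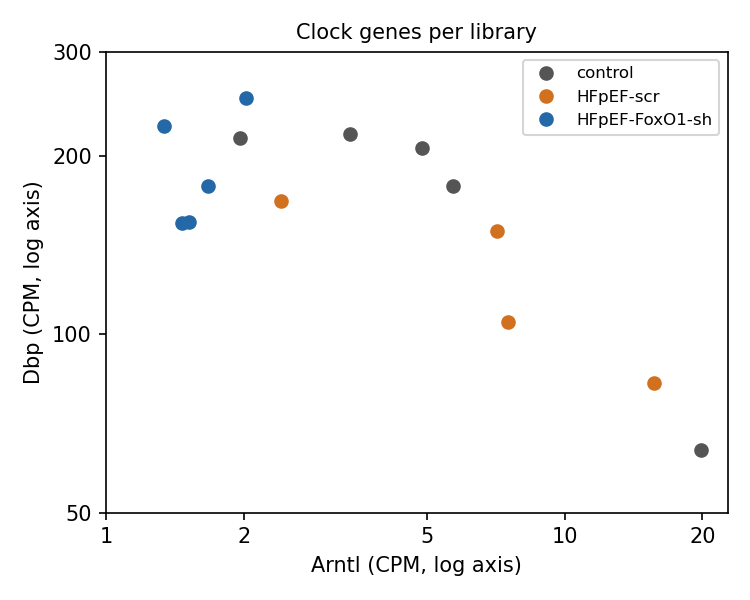
Arntl against Dbp in counts per 1000000 (CPM, both axes logarithmic) in each of the 14 libraries, coloured by group. The 5 libraries labelled HFpEF-FoxO1-sh lie between 1.34 and 2.02 CPM of Arntl, with 1 control at 1.95 among them.

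The count of 486 genes fell to 245 without HFpEF-scr 1, 314 without HFpEF-scr 2, 279 without HFpEF-scr 3, and 162, 253, 241 and 198 without HFpEF-FoxO1-sh 1, 2, 3 and 4. DESeq2 gave 876, a fold of 1.2 gave 16, the immediate early score as a covariate 254, and leaving out both HFpEF-scr 1 and 2, the libraries with the highest such scores, 54.

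HFpEF-FoxO1-sh against control asks how far hearts labelled with both the regime and the hairpin against Foxo1 lie from hearts on a standard diet. Of 23 genes of fatty acid oxidation 19 rose, and 20 of 41 matrix genes, 11 of 26 cell cycle genes and 11 of 15 antigen presentation genes fell. With an estimated correlation none of the 37 lists was called by camera (lowest adjusted p = 0.0978, with 10 lists at an unadjusted p under 0.05). Decr1 rose by 0.83 ± 0.06. Prnd, a relative of the prion protein gene, fell by 2.49 ± 0.29 (adjusted p = 4.53e-05), Nppb by 1.78 ± 0.28 (adjusted p = 7.54e-04) and Apln, which encodes the peptide apelin, by 1.59 ± 0.22 (adjusted p = 2.45e-04). In all, 1760 genes changed, 907 up and 853 down, of which 36 rose and 80 fell by at least 2-fold.

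Called genes that rose without overlap of the groups included Rpl14-ps1, Chrna2, Pde11a, Acot1, Sfrp5, Tcf23, Lgals4, Lrp2bp and Scn4b, from 3.42 ± 0.97 for Rpl14-ps1, a pseudogene, to 1.13 ± 0.08 for Scn4b (adjusted p = 1.13e-06). Sfrp5, a secreted antagonist of Wnt signals, rose by 1.64 ± 0.39. The 10 largest falls of that kind were Prnd, Mki67, Top2a, Nppb, Abat, Scgb1c1, Apln, Lrrc4b, Cpxm2 and C7, ending at -1.51 for C7. Mki67 fell by 2.00 ± 0.29 (adjusted p = 3.55e-04) and Top2a, the topoisomerase of dividing cells, by 1.82 ± 0.32. Only Rpl14-ps1 lost its call in refits without 1 library, in 6 of 10, with adjusted p up to 0.0672 without control 3. In GRCm38 Apln lies on the X chromosome at 48025146 to 48034853 and Prnd on chromosome 2 at 131950861 to 131956130.

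Of 23 genes of fatty acid oxidation 19 rose, 22 when adjusted over the list alone, with a median of 0.39 (list adjusted p = 1.15e-25, and adjusted p = 0.0978 with an estimated correlation). Of 30 genes of lipid handling and PPAR targets 17 rose, 19 when adjusted over the list alone, with a median of 0.29 (list adjusted p = 1.55e-11, and adjusted p = 0.0978 with an estimated correlation), among them Fabp3 by 0.62. Of 65 nuclear genes of oxidative phosphorylation 21 rose and 4 fell, 30 and 4 when adjusted over the list alone, with a median of 0.07 (list adjusted p = 1.47e-07, and adjusted p = 0.523 with an estimated correlation). Sdhc, an anchor subunit of complex II, rose by 0.33 ± 0.04. Of 25 genes of oxidative stress defence 6 rose and 1 fell, the same when adjusted over the list alone, with a median of 0.08 (list adjusted p = 0.00171, and adjusted p = 0.0978 with an estimated correlation). The superoxide dismutase gene Sod1 rose by 0.39 and Cat by 0.54. Of 27 genes of cholesterol and fatty acid synthesis 3 rose and 5 fell, 3 and 10 when adjusted over the list alone, with a median of -0.13 (list adjusted p = 0.00543, and adjusted p = 0.0978 with an estimated correlation). Srebf2, the activator of cholesterol synthesis, fell by 0.45, and Me1, which makes NADPH for lipid synthesis, rose by 0.53.

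Of 41 genes of extracellular matrix and fibrosis 20 fell and 1 rose, 21 and 1 when adjusted over the list alone, with a median of -0.44 (list adjusted p = 1.86e-11, and adjusted p = 0.0978 with an estimated correlation). Col3a1 fell by 1.07 ± 0.11 and Fbn1, the microfibril protein fibrillin, by 1.03 ± 0.11. Of 26 cell cycle genes 11 fell, 16 when adjusted over the list alone, with a median of -0.83 (list adjusted p = 1.18e-08, and adjusted p = 0.176 with an estimated correlation). Of 15 antigen presentation genes 11 fell, the same when adjusted over the list alone, with a median of -0.49 (list adjusted p = 1.77e-08, and adjusted p = 0.176 with an estimated correlation). The class II genes H2-Eb1 and Cd74 fell by 0.71 ± 0.11 and 0.62. Of 19 macrophage markers 11 fell, 15 when adjusted over the list alone, with a median of -0.52 (list adjusted p = 3.26e-08, and adjusted p = 0.176 with an estimated correlation), among them Csf1r, the receptor that macrophages need to survive, by 0.60. Of 22 sarcomere genes 7 fell, the same when adjusted over the list alone, with a median of -0.06 (list adjusted p = 8.66e-04, and adjusted p = 0.257 with an estimated correlation). Of 40 ion channel genes 5 rose and 6 fell, 5 and 7 when adjusted over the list alone, with no call for the list (adjusted p = 0.903, with a mean of -0.01, a median of 0.02 and an upward test). Kcnv2 rose by 0.87, and Gja1 fell by 0.45. Of 31 interferon response genes 5 fell, 9 when adjusted over the list alone, with a median of -0.17 (list adjusted p = 2.47e-05, and adjusted p = 0.176 with an estimated correlation). Of 23 autophagy genes 8 rose and 1 fell, 11 and 1 when adjusted over the list alone, with a median of 0.13 (list adjusted p = 6.43e-04, and adjusted p = 0.110 with an estimated correlation). Of 26 FoxO target genes 5 rose and 1 fell, 6 and 1 when adjusted over the list alone, with a median of 0.09 (list adjusted p = 0.0267, and adjusted p = 0.559 with an estimated correlation). That call was lost without control 1 (adjusted p = 0.0896), control 2 (0.0617) and HFpEF-FoxO1-sh 5 (0.169).

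Arntl fell by 2.21 ± 0.60 (adjusted p = 0.0239), a call lost in 4 of 10 refits (adjusted p up to 0.0779, without control 1). With the clock index as a covariate 624 genes changed in place of 1760, and 218 against a fold of 1.2.

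**Figure D4:**
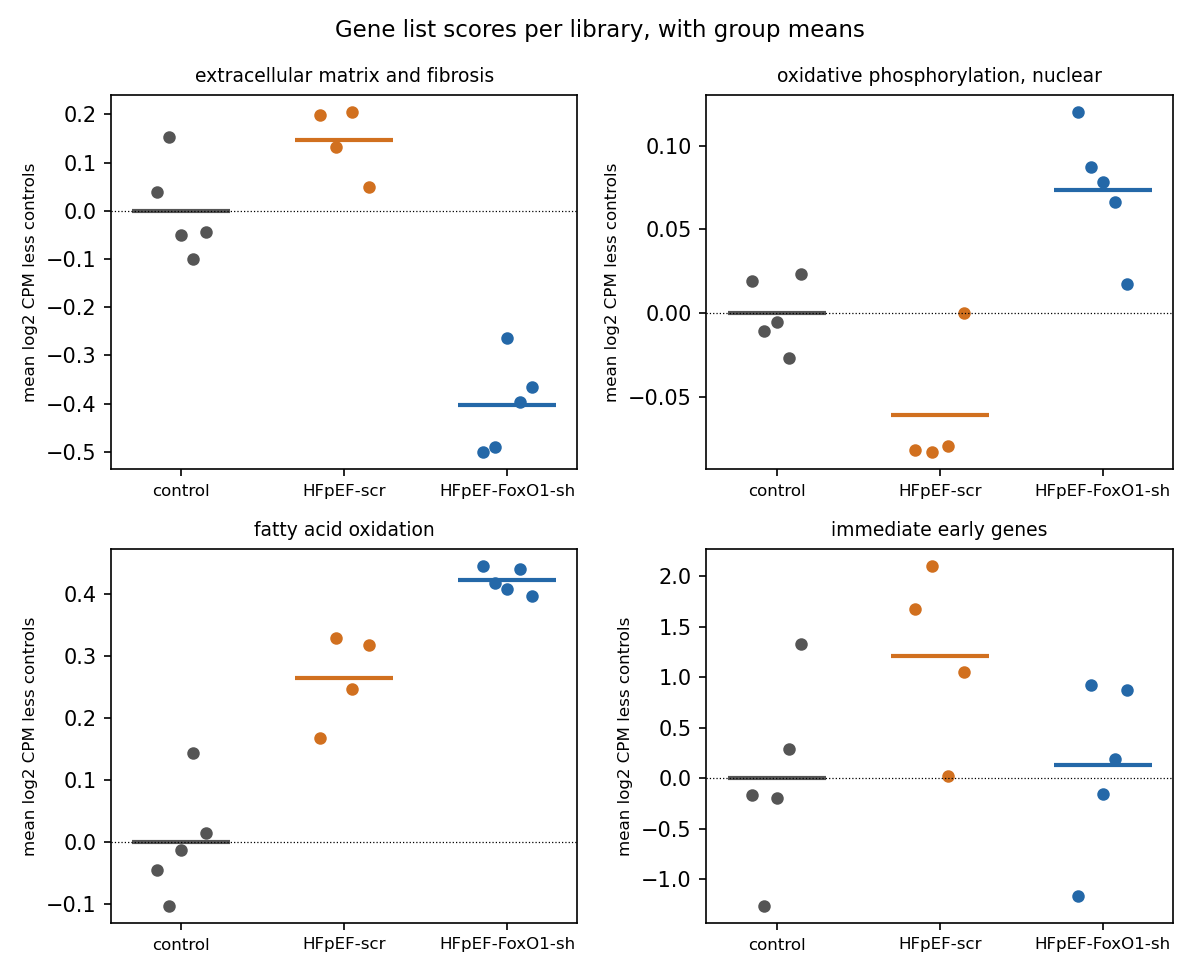
Mean log2 CPM of the members of 4 gene lists in each library, less their mean over the controls, by group, with bars for group means. Matrix scores lay between 0.05 and 0.20 in HFpEF-scr and between -0.50 and -0.26 in HFpEF-FoxO1-sh, and immediate early scores overlapped between all 3 groups.

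Genes that changed in HFpEF-scr against control and changed the other way in HFpEF-FoxO1-sh against HFpEF-scr numbered 116, with 61 up then down and 55 down then up. Those that changed the same way in both numbered 9. Gpt, the alanine transaminase, fell by 0.51 ± 0.09 and then rose by 0.50 ± 0.09, with 47.8, 33.5 and 47.5 CPM in control, HFpEF-scr and HFpEF-FoxO1-sh. Ldhb fell by 0.30 ± 0.03 and then rose by 0.18 ± 0.03, and Mpc1, a carrier of pyruvate into mitochondria, fell by 0.20 and then rose by 0.17. Antxr1, Aoc3, S100a10, Prelp and Osmr rose and then fell, and Cngb3 fell and then rose. Fosb went from 5.73 to 188 and back to 3.98 CPM. The comparisons share the HFpEF-scr libraries, which by itself sets their errors against each other. Independent lists of these sizes would hold 17.9 opposite pairs on average, and 40 simulated data sets without any change but with the shared libraries held 0.025 on average and at most 1. As no gene was changed in those data sets, few calls could arise in either comparison. Their count therefore gives no chance level for the 116. When the 4 HFpEF-scr libraries were split so that each comparison used 2 of them, 6 such fits gave 1 to 18 opposite pairs, with a median of 7, and 0 to 64 in the same direction, with a median of 5.5. Across genes, which are not independent replicates, the log2 fold changes of these comparisons had a Pearson correlation of -0.496. In the simulated data it was -0.559 ± 0.0418 (SD). That value comes from shared errors alone and real changes alter it, so it gives no chance level either. With separate HFpEF-scr libraries the correlation lay between -0.211 and -0.00905. The covariance was -0.0375, against -0.0207 ± 0.0028 (SD) in the simulated data and between -0.0218 and -0.00112 with separate libraries. The count of 116 became 220 with DESeq2, 41 in fits of 2 groups, 13 without HFpEF-scr 1 and 2, 1 against a fold of 1.2, 44 with the immediate early score as a covariate and, in edgeR with the clock index, 0, where 493 opposite pairs had an unadjusted p under 0.05 in both against 898 without it. It ran from 34 without HFpEF-FoxO1-sh 1 to 177 without control 1.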

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

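The tests of Foxo1 counts, of swapped libraries, of dilution by other cells and of the share of fibroblasts were chosen only after the result was seen, as were both covariates, the thinning of counts and the permutation test of the clock arms. The permutation tests of both scores between groups rest on those covariates. A sample far from the others of its group was found in 18 of 426 groups of values, or 4.2%, and chance alone does so in about 1 in 20. Control 1 held 21.25 M counts against 13.17 to 15.11 M in the other controls, and it also stood apart in Arntl (19.8 CPM), Adam19 (51.9 CPM), Kcnh2 (112 CPM) and Bckdhb (66.3 CPM). Among the other controls, Lgals4 was at 99.0 CPM and Bdh1 at 75.5 CPM in control 4, and Fbn1 at 109 CPM with a cholesterol and fatty acid synthesis score of 0.081 in control 2. HFpEF-scr 1 stood apart in Hbb-b1 (2364 CPM, against 205 to 398 in the rest of its group), in Antxr1 (15.2 CPM) and in its calcium handling score of -0.070. HFpEF-scr 4 did so in Tcf23 (6.66 CPM), in Cyp4f17 (1.98 CPM) and in its oxidative phosphorylation score of 2.5e-05, and HFpEF-scr 3 in Erdr1 (7.75 CPM). In HFpEF-FoxO1-sh it was Bhlhe40 in replicate 2 (77.0 CPM) and a FoxO target score of 0.42 in replicate 5.

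Chance was unlikely as the source of the 3 counts of changed genes. Of 126 possible splits in each comparison 100 were fitted. Only the real split, 1 of 100, gave as many, which is the lowest share that 100 splits can give. The real count and the highest of the other splits were 1001 and 490 for HFpEF-scr against control, 486 and 21 for HFpEF-FoxO1-sh against HFpEF-scr, and 1760 and 1 for HFpEF-FoxO1-sh against control. The split with 490 set controls 2 to 5 against control 1 and the HFpEF-scr libraries.

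Foxo1 was not lower in the libraries labelled HFpEF-FoxO1-sh than in HFpEF-scr by any called amount. Too few counts were excluded as the reason, because the 95% interval of its change ends at -10.9%, short of the fall of 25% that was set as the bound after the data were seen. A swap between the HFpEF groups that hid a fall of Foxo1 in whole tissue was excluded too. It would leave a library with a low level, and the lowest of any HFpEF library was 89.3% of the control mean. If the hairpin causes no such fall, a swap could not be seen in Foxo1. Silencing in muscle cells that is diluted by Foxo1 of other cell types might leave whole tissue as it is, and it stays open. The FoxO target genes went both ways, 11 below and 15 above 0, with a median log2 fold change of 0.021. Their mean score went from 0.28 in HFpEF-scr to 0.16 in HFpEF-FoxO1-sh, a fall with an SE of 0.104. Median and score thus differed in direction. Loss of the protein alone, or a hairpin that did not act, are biological readings that were not tested.

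Matrix genes were lower in HFpEF-FoxO1-sh than in HFpEF-scr, 21 of them called. A lower share of fibroblasts, as tracked by 6 markers that encode no matrix protein, did not account for the whole fall. These markers lay above the 14 collagens by 0.49 ± 0.06 (SE), with medians of -0.14 and -0.68. A shift between kinds of fibroblasts, or in other cells that make collagen, is not covered by that contrast and was not excluded. With the immediate early score as a covariate 21 stayed called, so that score did not account for these falls. It also ended all 5 calls of immediate early genes, but it is their own mean, so this is no check of the covariate. Acute handling that acts apart from that score was not excluded. Depth hardly differed between these groups, with mean totals of 14.5 M in HFpEF-scr and 14.6 M in HFpEF-FoxO1-sh. All 21 stayed called after thinning, which adds little, since the totals were already so close. Hour of collection cannot be told apart from the group, since the clock index of each HFpEF-FoxO1-sh library lay below that of each HFpEF-scr library: with it as a covariate 8 stayed called, and the median of all 21 went from -0.72 (median SE 0.0995) to -0.63 (median SE 0.109). In the other 13 the median went from -0.69 (median SE 0.109) to -0.57 (median SE 0.144), all with an unadjusted p under 0.05, and 9 of them would still have passed the largest p called before, but that limit moved from 0.00179 to 3.16e-05 as fewer genes had a small p. An action of the hairpin on matrix genes may remain a candidate explanation but was not shown.

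Clock genes differed between libraries in the way that different hours of collection would give. After taking out group means, Arntl, Npas2 and Clock ran against Dbp, Per2, Per3 and Tef, with a median correlation over 12 pairs of -0.865 and each pair below 0. The means of these arms had Pearson r = -0.973 (permutation p = 8e-05) and Spearman rho = -0.934 (permutation p = 1.7e-04) over 14 libraries, and r = -0.909 without the 2 farthest ones. Whether the libraries labelled HFpEF-FoxO1-sh differ as a group cannot be told apart from their hour, as only 1 library of the other groups, control 4, lay within or below their range of Arntl, and the labels give no hour. A candidate explanation is that these hearts were taken within a narrow window, and an effect of the hairpin on the clock was not tested.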

How the results depend on the processing

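The covariates, the pair left out and the thinning were chosen only after the data were seen. For genes and lists named in the text, 3806 of 4320 values kept direction and side of the threshold, and 30 turned direction. Of 45 genes named for HFpEF-FoxO1-sh against HFpEF-scr, the clock index ended 40 calls, leaving out HFpEF-scr 1 and 2 ended 37 and the immediate early score 18. Leaving out 1 library ended the call of 629 of 1001, 356 of 486 and 780 of 1760 genes in at least 1 refit (HFpEF-scr against control, HFpEF-FoxO1-sh against HFpEF-scr, HFpEF-FoxO1-sh against control), and turned none. The correlation of fold changes ran from -0.628 to -0.432 without 1 library. It moved by less than its jackknife SE of 0.198 in 19 alternatives. That SE was computed from the refits without 1 library, which are among these alternatives, so this is no test of stability. Small changes were partly missed, as 71.4% to 74% of simulated 1.5-fold changes were recovered. A test against a fold of 1.2 lowers counts by construction, and otherwise the cause was not tested, except for matrix genes with the clock index. Without 1 library the counts of changed genes ran from 537 to 1106 and from 162 to 668 for HFpEF-scr against control and HFpEF-FoxO1-sh against HFpEF-scr, and changed-back genes from 34 to 177. A fold of 1.2 gave 56, 16, 218 and 1 (the 3 comparisons in that order, then changed back), the immediate early score 396 and 254 with 44 changed back, and the clock index 11 and, against control, 624, with 0 changed back (1 coefficient more in edgeR, and 493 opposite pairs at an unadjusted p under 0.05). Without HFpEF-scr 1 and 2 there were 560 and 54, with 13 changed back, DESeq2 gave 876 in HFpEF-FoxO1-sh against HFpEF-scr and 220 changed back, and fits of 2 groups 504 in HFpEF-scr against control and 41 changed back. With the replicate number as a replicate block, which the labels do not explain, 291 genes changed in HFpEF-FoxO1-sh against HFpEF-scr and 76 changed back. After taking out group means, 13 pairs of libraries with the same number had correlations from -0.194 to 0.111, and 2 libraries correlated best with their own number. Camera with estimated correlations called 0, 1 and 0 lists, with 5, 9 and 10 at an unadjusted p under 0.05. Foxo1, never called, ran from -0.071 to 0.019 and from -0.075 to 0.015 without 1 library in these comparisons, and in the latter gave 0.029, 0.010 and 0.064 with the immediate early score, the clock index and without HFpEF-scr 1 and 2. In HFpEF-scr against control, medians without 1 library ran from -0.033 to -0.0083 for calcium handling (-0.015 without HFpEF-scr 1 and 2), from -0.069 to -0.0012 for ketone metabolism and from -0.68 to 1.35 for red cell markers (-0.68 without the pair, 0.61 with the immediate early score). Foxo3 ran from -0.21 to 0.054 (0.011 with the block, 0.040 with the clock index, 0.18 without the pair), and Hbb-b1 from -0.50 to 1.25 (-0.054 with limma voom with quality weights, -0.51 without the pair). Immediate early genes turned to -0.072 and 0.081 with their own score, and clock genes to -0.099 with theirs. FoxO targets in HFpEF-FoxO1-sh against HFpEF-scr ran from -0.033 to 0.069 (-0.0048 with the block, -0.051 with the clock index), and ion channels in HFpEF-FoxO1-sh against control from -0.0092 to 0.053 (0.016 in fits of 2 groups, -0.020 with the clock index).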

Other observations

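No test in this part was chosen after its result was seen, but the choice to describe this list was made after its values were seen. Genes of ketone metabolism moved in both directions in HFpEF-scr against control. Of 7 tested 2 rose and 2 fell, and the list was not called, with an upward test (adjusted p = 0.706). Acat1, an acetyl-CoA acetyltransferase of mitochondria, rose by 0.32 ± 0.05. Oxct1, the enzyme that lets tissues burn ketone bodies, fell from 1592 to 1251 CPM, by 0.35 ± 0.04 (adjusted p = 1.49e-04). Bdh1, which interconverts the main ketone bodies, fell by 1.13 ± 0.29 (adjusted p = 0.0281), a call lost in 5 of 9 refits without 1 library (adjusted p up to 0.0822, without HFpEF-scr 4). In HFpEF-FoxO1-sh against HFpEF-scr the list was not called either (adjusted p = 0.466).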
